A study of Mus musculus with 8 samples.

How the data were processed

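The series measured poly(A) RNA in bulk hippocampal tissue of mice by sequencing. It held 8 libraries: 4 from Dclk3 knockout (KO) animals and 4 from wild-type (WT) animals, all aged 12 months. Each library was made from 1000 ng of total RNA taken from a single hippocampus, with a strand-specific kit that marks the second strand with dUTP and with 12 cycles of PCR, per the labels' protocols. The labels do not state whether the 4 libraries of a group came from 4 different animals, so every p-value measures the spread between these samples, part of which may be technical. The part of Dclk3 removed in the KO animals, the strain and the litters are not given in the sources used here.

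The values analysed were whole-number read counts per Ensembl gene, deposited by the authors as raw counts without normalization, 1 column per library. Reads were demultiplexed with bcl2fastq 2.17.1.14 and the genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here. Genes that overlap another gene, and genes with near-identical copies, were therefore treated as uncertain, because the counting rule decides where shared reads go. The table listed 31417 genes, of which 2353 had no count in any library. Symbols were found for 31292 gene IDs and 125 IDs had none. Positions and gene classes came from the GENCODE M21 annotation of the same build, and 32 tested genes had no position there.

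Libraries held between 29301974 and 36552757 counts, so that 1 count equalled 0.0274 to 0.0341 CPM, the usual unit of counts scaled to the library total. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between pairs lay between 8.85 and 40.9 over genes with a summed count of at least 20. All 8 libraries were kept as separate replicates. PCR reads without molecular identifiers are not independent molecules, so counting intervals cover counting error alone.

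KO was compared with WT by edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, a robust quasi-likelihood F test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The filter left 16228 genes. CPM values were scaled with the same factors, and the standard error (SE) of a log2 fold change was its size divided by the square root of F. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it, each adjusted over the 31 lists. A list score is the mean over its genes of log2 CPM centred on the 8 libraries. Single values were compared by exact two-sided permutation tests over the 8 libraries, where 4 against 4 allows no p below 0.0286.

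The 31 lists, the main test, the rule for naming genes and most alternatives were fixed before the data were examined. The lists held 824 entries, 816 of which were found in the table. The rule named Dclk3; in each direction up to 12 called genes with the lowest p, filled to 5 where fewer passed; up to 4 members with the lowest p from each list; and the measured sex-linked genes. Genes with Gm or Rik names and pseudogenes were skipped in the ranking. Within the limit of 4, 3 members were named from lists called with the preset correlation and 2 from the others. Other genes that are named were chosen after their values were seen.

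The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, DESeq2 size factors or upper quartile factors within edgeR, no filter or a filter of 1 CPM in 4 libraries, dispersion without robust estimation, the replicate number as a block, a choroid plexus score or 1 surrogate variable from sva 3.50.0 as a covariate, thresholds of 0.1 and 0.01, and each library left out in turn. A test of genes near Dclk3 compared genes whose midpoint lies within 20 Mb of that gene with all others by a two-sided Fisher exact test, with 5 and 10 Mb as alternatives. No fit with sex as a covariate was made, since every library held counts of Y-linked genes.

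The pipeline was tested on simulated data before use. Counts were drawn for the comparison of KO with WT from the means, dispersions and library sizes of these samples, with 50 genes at each of 4 fold sizes, and 16071 genes passed the filter. At folds of 1.5, 2, 4 and 8, edgeR recovered 60%, 72%, 92% and 98% of the changed genes. It called 173 genes, 9 of them not changed, while DESeq2 called 34 genes that were not changed. A list raised 1.2-fold was recovered under both camera settings, and the preset correlation also called 2 lists that had not been raised. Simulated genes were drawn independently, while estimated correlations in the lists called from the real samples were 0.11 to 0.60. The simulation therefore does not show how often correlated genes or lists would be recovered or wrongly called. Values of 3 single genes are not reported here. Figures were drawn with matplotlib 3.10.9.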

Results

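Gene expression in the hippocampus was compared between 12-month-old Dclk3 knockout (KO) mice and wild-type (WT) mice by stranded poly(A) RNA sequencing. Dclk3 encodes doublecortin-like kinase 3, a serine/threonine kinase enriched in the brain. There were 4 KO and 4 WT libraries. Total counts per library were 36552757, 32531464, 30387045 and 30602055 for WT replicates 1 to 4, and 35268128, 29449183, 29301974 and 31910242 for KO replicates 1 to 4. The 10 most abundant genes took between 5.21% and 6.24% of the counts of a library. The first principal component of log2 CPM held 26.7% of the variance and did not part the genotypes: WT replicate 2 lay at 35.8 on it and KO replicate 1 at -26.1.

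Dclk3 (ENSMUSG00000032500, mm10 9:111439081 to 111489118, plus strand, protein coding) was examined first, because it checks the genotype labels. Its level was 26.7 ± 8.51 CPM in WT and 7.71 ± 1.42 CPM in KO (mean ± SD, n = 4 each), so that KO libraries held 28.9% of the WT level. The 4 KO libraries had 301, 281, 171 and 233 counts, and the 4 WT libraries had 828, 1261, 649 and 695. Every KO library lay below every WT library, from 5.92 to 9.29 CPM against 20.8 to 39.3 CPM. The exact Poisson interval (95%) of the lowest KO count, 171, ran from 146 to 199 counts, so the remaining counts in KO were far above zero. Which part of the gene these reads cover cannot be read from counts per gene. The fitted log2 fold change was -1.79 (SE 0.22), a level 3.45-fold lower in KO. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give.

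Over all genes, edgeR did not call Dclk3 (adjusted p = 0.234), while DESeq2 did (adjusted p = 5.25e-14). WT replicate 2 widened the WT spread with 39.3 CPM. Without that library the log2 fold change was -1.54 and edgeR called the gene (adjusted p = 0.0121). With any other library left out, the edgeR adjusted p of Dclk3 was 0.123 to 0.997.

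**Figure D1:**
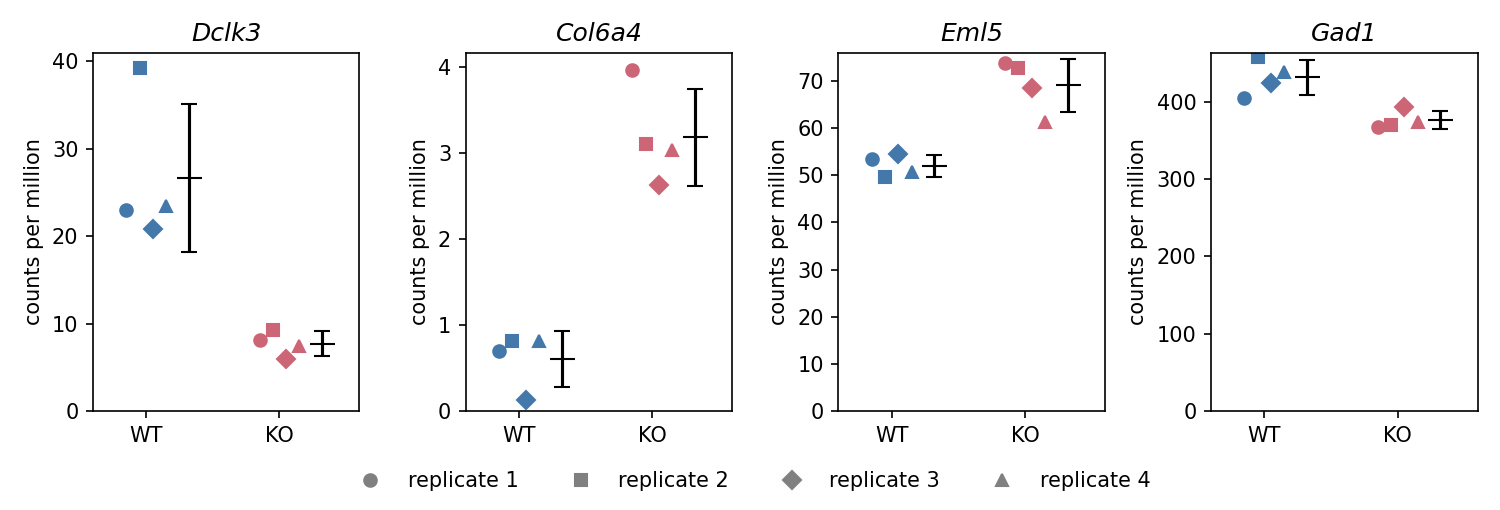
Expression in CPM of Dclk3, Col6a4, Eml5 and Gad1 in each of the 8 libraries, with each axis starting at 0. Points are libraries, with a marker shape per replicate number that does not imply pairing. Black lines are the mean ± SD of 4 libraries per genotype. For each of the 4 genes the KO and WT libraries do not overlap. Col6a4, Eml5 and Gad1 were named for a low p, so for them that separation is not further evidence.

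Beyond Dclk3, the genes with the lowest p were Col6a4, Eml5, Zcchc7, Gabpb2 and Ftx on the higher side of KO, and Oprl1, Ajap1, Zfyve1 and Slc5a5 on the lower side. None of them was called by edgeR at an adjusted p under 0.05, and each had all 4 KO libraries outside the WT range. The genes were picked for a low p, so that separation is not further evidence. For Slc5a5 the nearest values were 28.76 CPM in KO replicate 1 and 28.86 CPM in WT replicate 1. Col6a4 (ENSMUSG00000032572, mm10 9:105989454 to 106096783), which encodes a chain of type VI collagen, stood at 0.611 ± 0.326 CPM in WT and 3.19 ± 0.564 CPM in KO. Its log2 fold change was 2.38 (SE 0.37; edgeR adjusted p = 0.463; DESeq2 adjusted p = 1.09e-07). It is a low-abundance gene with 4 to 26 counts in WT and 76 to 146 counts in KO libraries. Leaving out WT replicate 3, which had 4 counts, brought Col6a4 to an edgeR adjusted p of 0.0479, with a log2 fold change of 2.05. With any other library left out, the edgeR adjusted p of Col6a4 was 0.172 to 0.997.

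Eml5 (ENSMUSG00000051166, mm10 12:98786805 to 98901484), a microtubule-associated protein gene, had 52.0 ± 2.33 CPM in WT and 69.0 ± 5.61 CPM in KO, a log2 fold change of 0.41 (SE 0.07; edgeR adjusted p = 0.463). Zcchc7 (ENSMUSG00000035649), whose product takes part in nuclear RNA surveillance, had 23.1 ± 1.16 and 30.7 ± 2.55 CPM, a log2 fold change of 0.41 (SE 0.07; edgeR adjusted p = 0.526). Ftx (ENSMUSG00000086370), a long noncoding RNA of the X inactivation centre, had 9.95 ± 1.69 and 15.1 ± 1.21 CPM, and Gabpb2 (ENSMUSG00000038766), a subunit of the GABP transcription factor, 21.96 ± 1.11 and 27.4 ± 1.53 CPM. On the lower side, Oprl1 (ENSMUSG00000027584), the nociceptin receptor, had 64.4 ± 2.85 CPM in WT and 52.5 ± 3.49 CPM in KO (log2 fold change -0.30, SE 0.06). Ajap1 (ENSMUSG00000039546), an adherens junction protein, had 42.9 ± 2.50 and 36.3 ± 1.08 CPM. Zfyve1 (ENSMUSG00000042628), which binds phosphoinositides on endoplasmic reticulum membranes, had 54.2 ± 0.988 and 47.5 ± 0.776 CPM. Slc5a5 (ENSMUSG00000000792), the sodium iodide symporter, had 31.9 ± 2.11 and 24.2 ± 3.27 CPM. The edgeR adjusted p was 0.796 for Gabpb2, Ftx and these 4 genes.

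edgeR called 0 of 16228 genes. At an unadjusted p under 0.05 there were 1000 genes, 643 with a higher and 357 with a lower level in KO, where chance gives 811.4. DESeq2 called 5 of 15580 genes, namely Dclk3 as lower and Col6a4, Eml5, Zcchc7 and Ftx as higher; limma-voom with quality weights called 0. The 2 genotypes did not overlap in 617 genes, 3.80% of those tested, where chance gives 2.86%. The biological coefficient of variation was 13.3% and the median SE of a log2 fold change was 0.105. In simulated data of this size edgeR recovered 72% of genes at a 2-fold change. Simulated genes were drawn independently and 173 were called, which loosens the adjusted threshold, so that share does not carry over to these samples. Here Dclk3, 3.45-fold lower, and Col6a4, 5.19-fold higher in KO, were not called by edgeR. Leaving out WT replicate 4, KO replicate 2 or KO replicate 4 moved the 1000 genes to 556, 640 or 1777.

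Among 31 gene lists, camera with a preset correlation called 11, of which 6 lay higher and 5 lower in KO. With an estimated correlation it called 0 lists, and fry called 0 lists. Estimated correlations in the called lists were 0.11 to 0.60. Splits of the libraries that mixed the genotypes called 5 to 19 lists with the preset correlation. For exact permutation of the list scores, the lowest adjusted p over the lists was 0.886. No p from 4 against 4 can fall below 0.0286, so passing over 31 lists would need many lists at that floor together. The adjusted value therefore cannot speak for or against a single list. Before adjustment the lowest permutation p was 0.0571, for dentate granule cell markers and mitochondrially encoded genes. In no list was any member called by edgeR, either over all genes tested or adjusted over the list alone, where the count was also 0 for each list. Member counts given for the lists are therefore counts of the sign of the fold change. The number of lists called was 6 without WT replicate 4.

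Markers of dentate gyrus granule cells lay higher in KO: 17 of 18 had a log2 fold change above 0, with a median of 0.21 (camera adjusted p = 2.60e-05; adjusted p = 0.626 with an estimated correlation). Stxbp6 stood at 139.5 ± 12.2 CPM in WT and 168 ± 16.6 CPM in KO, Npnt at 30.2 ± 1.91 and 34.9 ± 2.56 CPM, and Rfx3, a ciliary transcription factor, at 129 ± 4.42 and 149.5 ± 18.6 CPM. The list score ranged from -0.28 in WT replicate 2 to 0.17 in KO replicate 4. Markers of CA1 pyramidal cells lay lower, with 12 of 14 below 0 and a median of -0.08 (camera adjusted p = 0.0404; adjusted p = 0.776 with an estimated correlation). Of these, Fibcd1 had 247 ± 29.4 and 209.8 ± 44.7 CPM and Nr3c2, the mineralocorticoid receptor, 281 ± 55.2 and 237 ± 45.1 CPM; the noncoding Gm10754 had 0.855 ± 0.187 and 0.513 ± 0.123 CPM. The CA1 call was lost without WT replicate 3, WT replicate 4, KO replicate 1 or KO replicate 4, with an adjusted p by camera of up to 0.341, and without WT replicate 4 the median was -0.046. CA3 and CA2 markers were not called, with 14 of 19 below 0, a median of -0.08 and an adjusted p of 0.198 by camera; without KO replicate 1 the median was -0.0041. Socs2 had 18.1 ± 1.70 and 15.7 ± 1.197 CPM and Cdh24 9.28 ± 1.02 and 10.8 ± 1.89 CPM.

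Genes of presynaptic vesicles and release machinery lay lower in KO, with 29 of 35 below 0 and a median log2 fold change of -0.10 (camera adjusted p = 2.07e-04; adjusted p = 0.776 with an estimated correlation). Syn2, a synapsin, stood at 943 ± 53.0 and 838 ± 37.7 CPM and Sv2b, a vesicle glycoprotein, at 766 ± 53.2 and 633 ± 98.7 CPM. The presynaptic call held in each of 8 fits that left out a library, with a median of -0.058 without WT replicate 4 and -0.064 without KO replicate 2. Exact permutation of the presynaptic score over the 8 libraries gave p = 0.114 (adjusted p = 0.886). GABA neuron markers lay lower, with 18 of 26 below 0 and a median of -0.10 (camera adjusted p = 0.0485; adjusted p = 0.776 with an estimated correlation). Gad1, the GABA-synthesizing enzyme, had 432 ± 22.6 CPM in WT and 376 ± 11.5 CPM in KO. The serotonin receptor gene Htr3a had 14.7 ± 0.791 and 12.0 ± 0.598 CPM. Neither gene overlapped between genotypes, but both were named for a low p in the list, so that separation is not further evidence. The edgeR adjusted p was 0.796 for both. Adarb2 went the other way, at 25.9 ± 3.09 and 31.7 ± 3.34 CPM. The GABA call was kept only without WT replicate 2 or KO replicate 1, and lost without any other library; without WT replicate 4 the median was -0.038 (camera adjusted p = 0.329). Cytoskeleton and transport genes lay lower, with 28 of 36 below 0 and a median of -0.07 (camera adjusted p = 0.0155; adjusted p = 0.776 with an estimated correlation). Dctn1, a dynactin subunit, had 429 ± 17.8 and 397 ± 8.16 CPM and the neuronal tubulin Tubb3 237 ± 11.05 and 216 ± 15.6 CPM, while Map7 had 69.5 ± 7.19 and 79.0 ± 2.78 CPM. The cytoskeleton call was lost without WT replicate 4, KO replicate 1 or KO replicate 2, with an adjusted p by camera of up to 0.225 and medians of -0.027, -0.0085 and -0.037 in that order. Without WT replicate 3 or KO replicate 4 the median was -0.10 or -0.12.

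The remaining neuronal lists were not called with either correlation over all 8 libraries, although 3 of them were called lower with the preset correlation when certain libraries were left out. Glutamate receptors and postsynaptic scaffolds had 30 of 42 members below 0 (median -0.05, camera adjusted p = 0.0826), with Grin3a at 59.4 ± 6.65 and 52.0 ± 3.18 CPM and Nlgn1 at 129.6 ± 6.39 and 114 ± 18.7 CPM in WT and KO. This list was called without WT replicate 3 or KO replicate 4 (camera adjusted p = 0.0149 and 0.0388), while its median was -0.0092 without WT replicate 4 (camera adjusted p = 0.507) and -0.018 without KO replicate 1. Voltage-gated potassium and calcium channels had 27 of 37 below 0 (median -0.04, camera adjusted p = 0.0758), with Cacnb1 at 155 ± 10.1 and 137 ± 10.1 CPM and Cacna1b at 148 ± 11.3 and 132 ± 15.4 CPM. The channel list was called without WT replicate 2, WT replicate 3, KO replicate 3 or KO replicate 4 (camera adjusted p = 0.0451, 0.00857, 0.0243 and 0.00426). Its median was -0.11 without KO replicate 4, -0.014 without WT replicate 4 and -0.0030 without KO replicate 1 (camera adjusted p = 0.712). Doublecortin family kinases and their calmodulin-dependent relatives had 6 above and 9 below 0 (camera adjusted p = 0.518). Dclk1, the best-known relative of Dclk3, had 847 ± 136 and 759.6 ± 52.9 CPM and Camk1g 30.3 ± 2.76 and 26.4 ± 3.68 CPM. Immediate early genes had 11 above and 14 below 0 (camera adjusted p = 0.335), with Gadd45b at 10.6 ± 1.39 and 8.29 ± 0.558 CPM and Ier2 at 4.15 ± 0.640 and 5.37 ± 0.392 CPM; they were called without KO replicate 3 (camera adjusted p = 0.00752), and their median lay above 0, at 0.018 to 0.045, without WT replicate 4, KO replicate 1 or KO replicate 2. Immature neuron and stem cell markers had 10 of 17 below 0 (camera adjusted p = 0.272), with Nes at 18.8 ± 1.63 and 16.8 ± 1.65 CPM, and a median of -0.04 that was 0.031 without KO replicate 2 and -0.16 without KO replicate 4.

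Markers of neighbouring regions were also not called. Cortical markers had 12 of 21 above 0 (camera adjusted p = 0.532), with Fam84b at 23.8 ± 3.55 and 31.9 ± 3.98 CPM and Scnn1a at 7.87 ± 1.141 and 10.3 ± 1.53 CPM; without KO replicate 1 the median was -0.054. Striatal markers had 9 above and 10 below 0 (camera adjusted p = 0.659), with Pdyn at 13.9 ± 3.42 and 17.9 ± 2.47 CPM and Pde10a at 88.5 ± 2.47 and 81.4 ± 6.89 CPM; their median was -0.03 and their mean 0.02, and camera placed them lower. With a library left out, the striatal median ranged from -0.082 without WT replicate 4 to -0.00092 without KO replicate 3. Thalamic and habenular markers had 15 of 19 above 0 (camera adjusted p = 0.518), with Zic4 at 3.22 ± 1.46 and 4.001 ± 0.691 CPM and Gpr151 at 0.894 ± 0.527 and 0.684 ± 0.130 CPM.

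**Figure D2:**
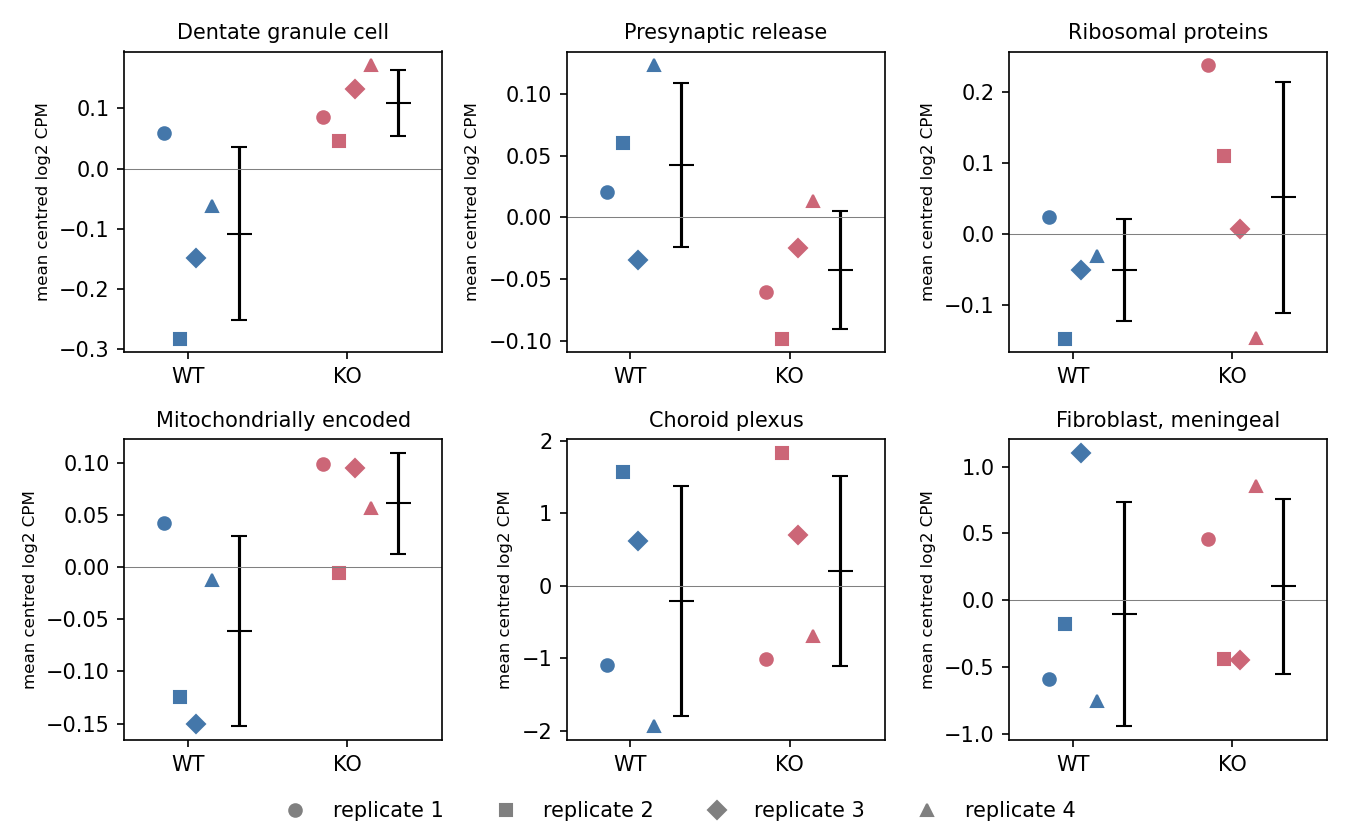
Scores of 6 gene lists (mean over the list of log2 CPM centred on the 8 libraries) in each library, by genotype. Points are libraries, with a marker shape per replicate number, and black lines are the mean ± SD of 4 libraries; the choroid plexus score spans -1.94 to 1.84 and varies within both genotypes far more than the scores of the dentate granule cell, presynaptic, ribosomal and mitochondrially encoded lists.

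Transcripts encoded by mitochondrial DNA lay higher in KO, with 7 of 7 above 0 and a median of 0.13 (camera adjusted p = 0.00263; adjusted p = 0.776 with an estimated correlation). Only these 7 of the 13 listed genes were tested. The complex I genes mt-Nd1, mt-Nd2 and mt-Nd4 had 6397 ± 342, 4032 ± 284 and 3768 ± 214 CPM in WT, and 7035 ± 374, 4544 ± 309 and 4176 ± 212 CPM in KO. Counts deposited for genes of the mitochondrial genome together took 3.58% to 3.90% of the counts in WT libraries and 3.92% to 4.41% in KO libraries. The listed genes that were not tested had no entry or did not pass the filter. This share may therefore not be that of the whole mitochondrial genome. Nuclear-encoded oxidative phosphorylation subunits were not called, with 45 of 70 above 0 and a camera adjusted p of 0.335, but called higher without WT replicate 1 or KO replicate 4 (camera adjusted p = 0.0425 and 0.0316). Their median was -0.013 without WT replicate 2 and 0.012 without KO replicate 1, where camera placed them lower. Among them Ndufa9 had 109.9 ± 1.28 and 102 ± 2.10 CPM. Atp5l had 1.93 ± 0.485 and 2.73 ± 0.492 CPM, a level that is uncertain because this gene has near-identical copies. Cytosolic ribosomal protein genes lay higher, with 65 of 74 above 0 and a median of 0.09 (camera adjusted p = 2.07e-04; adjusted p = 0.776 with an estimated correlation). Rpl34 had 30.1 ± 1.98 and 34.6 ± 2.69 CPM, Rpl13a 12.1 ± 1.16 and 14.1 ± 0.474 CPM and Rps24 64.6 ± 4.35 and 71.3 ± 3.39 CPM. Levels of this family are uncertain, since its many processed pseudogenes can take reads. The ribosomal call was lost without KO replicate 1 (median 0.052, camera adjusted p = 0.164), and without KO replicate 4 the median was 0.14.

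Cholesterol synthesis genes lay lower in KO, with 19 of 22 below 0 and a median of -0.11 (camera adjusted p = 0.00402; adjusted p = 0.776 with an estimated correlation). Sqle, squalene epoxidase, had 75.7 ± 9.03 and 64.2 ± 4.95 CPM and Hmgcs1, the cytosolic HMG-CoA synthase, 271 ± 24.3 and 235 ± 18.6 CPM. The cholesterol call was lost without WT replicate 4 or KO replicate 4, with medians of -0.061 and -0.072 and an adjusted p by camera of up to 0.150. Glucocorticoid-responsive genes lay higher, with 12 of 15 above 0 and a median of 0.19 (camera adjusted p = 0.0185; adjusted p = 0.776 with an estimated correlation). Tsc22d3 (GILZ) had 37.8 ± 3.67 and 46.6 ± 7.32 CPM, the phagocytic receptor gene Mertk 40.7 ± 5.05 and 51.9 ± 10.2 CPM, and Arrdc2 6.13 ± 0.291 and 7.18 ± 0.763 CPM. This list had a score of 0.50 in KO replicate 4 against -0.14 to -0.0011 in the other 3 KO libraries. Without KO replicate 4 the median was 0.08 and the call was lost (camera adjusted p = 0.535), as it was without WT replicate 3 (camera adjusted p = 0.0579). Heat shock and unfolded protein genes were not called, with 19 of 25 below 0 (camera adjusted p = 0.175), Hspa8 at 272 ± 12.1 and 249 ± 23.2 CPM and Bag3 at 11.6 ± 1.86 and 10.4 ± 0.783 CPM; they were called lower without WT replicate 4 (camera adjusted p = 0.0431), and their median was -0.012 without WT replicate 2 (camera adjusted p = 0.739). Chromatin modifiers were not called either (20 above and 23 below 0, camera adjusted p = 0.654); their median was -0.02 and their mean 0.00. In that list Tet2, a DNA demethylase, had 27.7 ± 1.99 and 31.98 ± 0.713 CPM and Hdac7 16.2 ± 1.74 and 21.3 ± 5.69 CPM.

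Among non-neuronal cells, oligodendrocyte lineage markers lay higher in KO, with 20 of 25 above 0 and a median of 0.12 (camera adjusted p = 0.0438; adjusted p = 0.776 with an estimated correlation). The myelin gene Mobp had 517 ± 106 CPM in WT and 647 ± 45.8 CPM in KO, and Trf, transferrin, 16.7 ± 1.35 and 19.4 ± 2.04 CPM. Gpr17, a marker of committed precursors, went the other way at 45.9 ± 4.33 and 38.7 ± 3.88 CPM. Blood cell markers lay higher, with 6 of 7 above 0 and a median of 0.53 (camera adjusted p = 0.0245; adjusted p = 0.776 with an estimated correlation). Only these 7 of the 16 listed blood markers were tested. The globin genes Hba-a1, Hba-a2 and Hbb-bt had 9.95 ± 1.77, 6.51 ± 0.994 and 8.90 ± 1.55 CPM in WT, and 14.3 ± 3.78, 9.75 ± 3.31 and 14.7 ± 5.65 CPM in KO, with KO replicate 2 inside the WT range for each of these 3. Reads of the globin copies can be exchanged between them, so their separate values are uncertain. The oligodendrocyte call was kept only without WT replicate 1, where the median was 0.22, or KO replicate 4. Its median lay between 0.062 and 0.078 without WT replicate 2, WT replicate 3, KO replicate 2 or KO replicate 3. The blood call was kept only without WT replicate 1 or KO replicate 2, with a camera adjusted p of up to 0.0925 without another library.

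Astrocyte markers were not called, with 17 of 20 above 0 (camera adjusted p = 0.0826); Ntsr2 had 67.3 ± 10.7 and 79.8 ± 11.2 CPM and Acsbg1 172 ± 18.0 and 189 ± 12.9 CPM. They were called higher without WT replicate 1 or KO replicate 2 (camera adjusted p = 0.00577 and 0.0162), and without KO replicate 1 the median was 0.032 (camera adjusted p = 0.668). Microglial and reactive immune markers had 19 of 25 above 0 (camera adjusted p = 0.138), with Aif1 at 5.40 ± 0.629 and 6.26 ± 0.577 CPM and Spi1 at 3.31 ± 0.411 and 3.96 ± 0.579 CPM; they were called higher without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3, with an adjusted p by camera of 0.0143 to 0.0443. Without KO replicate 4 or WT replicate 4 the microglial median was 0.00020 or 0.010. Interferon-stimulated genes had 13 above and 12 below 0 (camera adjusted p = 0.809), and camera placed them lower while the median was 0.00 and the mean -0.01. Ifit1 had 2.73 ± 1.03 and 1.79 ± 0.135 CPM and Ifi44 0.826 ± 0.0800 and 0.592 ± 0.0359 CPM. Endothelial and mural markers had 17 of 22 above 0 (camera adjusted p = 0.272), with Slco1a4 at 53.9 ± 4.32 and 60.6 ± 7.12 CPM and Abcb1a at 33.5 ± 4.58 and 39.3 ± 7.90 CPM, and were called higher without KO replicate 2 (camera adjusted p = 0.0143), while without KO replicate 4 their median was -0.035.

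Choroid plexus and meningeal markers, which come from tissue adjoining the hippocampus, differed between libraries within both genotypes. Ttr, the abundant choroid plexus transcript for transthyretin, took 0.00308% to 0.194% of the counts in WT libraries and 0.0146% to 0.324% in KO libraries. The choroid plexus list was not called, with 21 of 24 above 0 (camera adjusted p = 0.175); Msx1 had 6.27 ± 2.57 and 8.05 ± 3.72 CPM and Calml4 3.70 ± 1.85 and 4.71 ± 3.76 CPM. It was called higher without WT replicate 2 or KO replicate 1 (camera adjusted p = 1.31e-04 and 0.00635), while its median was -0.47 without KO replicate 2, -0.067 without WT replicate 4 and -0.024 without WT replicate 1. Fibroblast and meningeal markers had 15 of 20 above 0 (camera adjusted p = 0.165), with Cemip, a hyaluronan-binding protein gene, at 36.6 ± 2.20 and 46.8 ± 6.15 CPM and Bmp6 at 8.52 ± 4.45 and 10.4 ± 2.09 CPM. They were called higher without WT replicate 3, KO replicate 2 or KO replicate 3 (camera adjusted p = 6.73e-06, 0.0143 and 0.0182), while their median was -0.21 without KO replicate 4, -0.12 without WT replicate 4 and -0.083 without WT replicate 1. Ependymal cell and cilium markers had 13 of 19 above 0 (camera adjusted p = 0.218), with Ccdc39 at 11.5 ± 1.18 and 15.0 ± 2.04 CPM and Cfap44 at 4.08 ± 0.609 and 5.66 ± 1.34 CPM, and were called higher without KO replicate 1 (camera adjusted p = 0.00635), while without WT replicate 4 or KO replicate 2 their median was -0.047 or -0.035.

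All 8 libraries held counts of Y-linked genes. Ddx3y had 73.1 ± 6.03 CPM in WT and 72.3 ± 4.37 CPM in KO, Kdm5d 23.9 ± 1.92 and 24.8 ± 3.48 CPM, Uty 21.1 ± 1.19 and 20.3 ± 2.49 CPM, and Eif2s3y 20.6 ± 2.75 and 22.2 ± 11.9 CPM. Eif2s3y alone varied widely, from 7.10 CPM in KO replicate 4 to 36.3 CPM in KO replicate 1. Xist, the noncoding RNA of the inactive X chromosome, had between 0 and 3 counts per library. The list of sex-linked genes was not called (camera adjusted p = 0.760), and camera placed it lower while its median was 0.02.

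Gene classes of the annotation were compared after the data had been seen. The 1376 noncoding genes tested had a median log2 fold change of 0.14, and 71.3% of them lay above 0, against a median of -0.01 and 48.0% for the 14447 protein-coding genes. Of noncoding genes at an unadjusted p under 0.05, 138 were higher and 11 lower in KO. Medians were 0.12 for 417 lincRNAs, 0.10 for 369 antisense genes, 0.18 for 238 processed transcripts and 0.23 for 263 genes of the class TEC, which are annotated loci still to be experimentally tested. The mean level of noncoding genes ranged from -0.22 in WT replicate 2 to 0.20 in KO replicate 1 on the centred log2 scale, with KO replicate 4 at -0.07 among the WT values. The difference in that level between genotypes had an exact permutation p of 0.114 (adjusted p = 0.257 over 6 classes). The class TEC did not overlap between genotypes (exact permutation p = 0.0286, adjusted p = 0.171). That p is the smallest that 4 against 4 can give, so a single class could not pass the adjustment over 6 classes. Antisense genes, and genes inside others, are uncertain here because the use of strand in counting is not given.

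**Figure D3:**
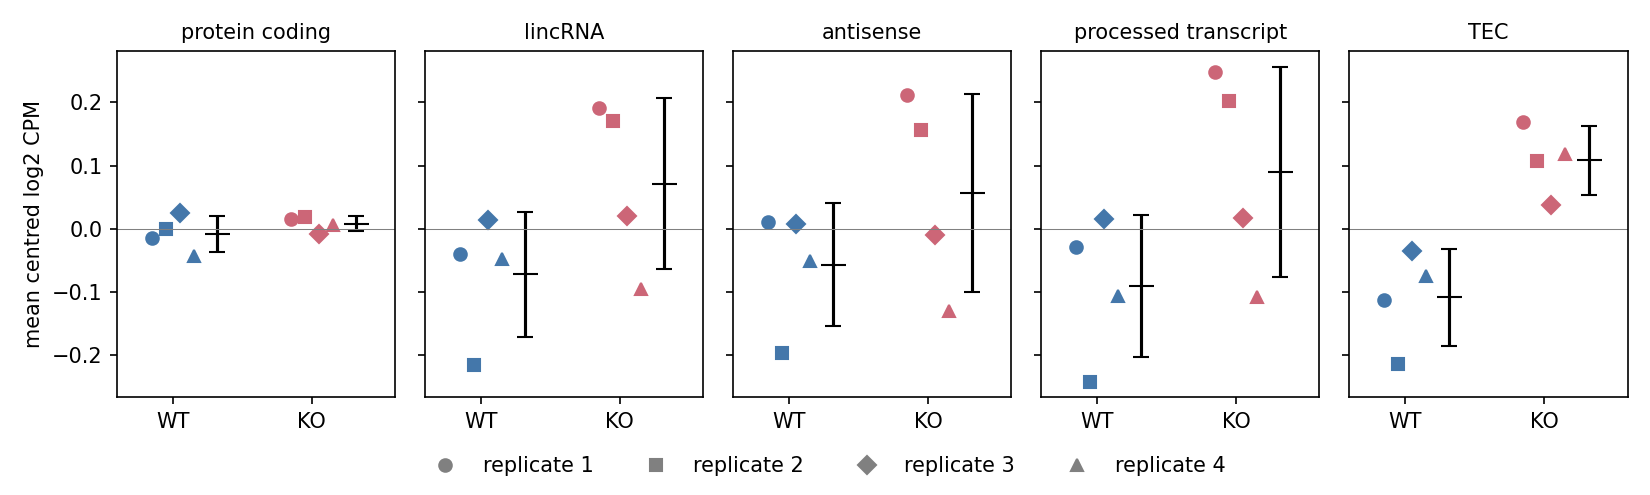
Mean over the genes of a class of log2 CPM centred on the 8 libraries, for protein-coding genes, lincRNAs, antisense genes, processed transcripts and TEC genes. Points are libraries, with a marker shape per replicate number, and black lines are the mean ± SD of 4 libraries; KO replicates 1 and 2 lie highest in the lincRNA, antisense and processed transcript classes, and WT replicate 2 lies lowest in each of the 4 noncoding classes.

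Genes around Dclk3 were compared with the rest of the genome, since a targeted line can carry chromosome segments of another strain next to the targeted gene. edgeR called 0 of 326 tested genes within 20 Mb of Dclk3 on chromosome 9, Dclk3 left out, and 0 elsewhere; DESeq2 called 1, Col6a4, whose midpoint lies 5.42 Mb away. At an unadjusted p under 0.05, a threshold added after the data had been seen, 34 of the 326 genes passed (10.4%), against 965 of 15901 elsewhere (6.07%). The odds ratio was 1.80 (95% interval 1.22 to 2.59, two-sided Fisher exact p = 0.00235), and 26 of the 34 lay higher in KO. The excess was not found closer to the gene: the odds ratio was 0.80 (0.32 to 1.70) within 5 Mb, with 7 of 140 genes, and 1.34 (0.78 to 2.19) within 10 Mb, with 18 of 223 genes. Neighbouring genes are not independent, so these intervals can be too narrow. Trank1, whose midpoint lies 0.110 Mb from that of Dclk3, stood at 119 ± 18.8 CPM in WT and 174 ± 49.96 CPM in KO (log2 fold change 0.55, SE 0.20). The collagen-modifying enzyme gene Plod2, 18.9 Mb away, had a log2 fold change of 0.50 (SE 0.12). Trank1 and Plod2 were chosen after their values were seen.

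**Figure D4:**
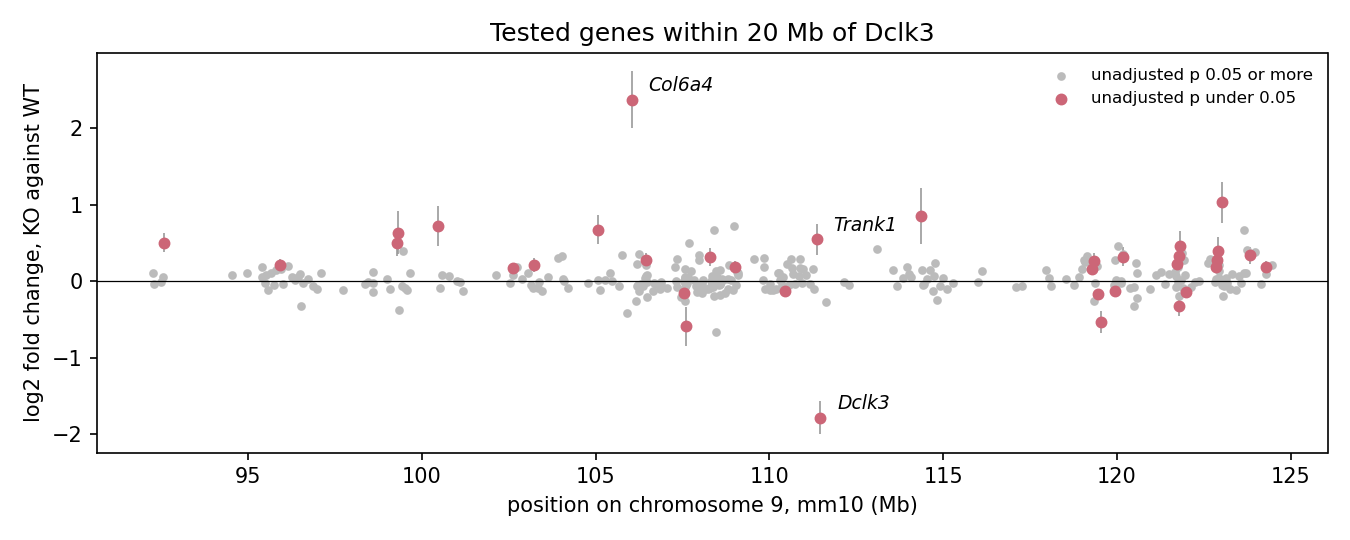
Log2 fold change of KO against WT for the tested genes within 20 Mb of Dclk3, by midpoint on chromosome 9 of mm10 in Mb. Red points are genes at an unadjusted p under 0.05, with bars of 1 SE, and grey points are the others; Dclk3 lies at -1.79 and Col6a4 at 2.38, and the other genes with red points lie between -0.59 and 1.03.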

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

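Values were picked out here when the highest or lowest of the 4 libraries of a group lay far from the other 3, by a gap above Dixon's 95% critical share of the whole range of the group. Of 232 groups tested 16 passed, where chance gives 11.6. For the reactive astrocyte genes, the 22-gene list and the tests of astrocyte share and of a wrong label were chosen only after the result was seen; the test of choroid plexus or meningeal tissue was not.

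WT replicate 2 stood apart in 5 of the genes. It had the highest Dclk3 level of the WT libraries, 39.3 CPM against 20.8 to 23.5 in the other 3, and the highest Gpr151 level, 1.68 CPM against 0.608 to 0.675. It had the lowest level of Adarb2 (21.3 CPM against 27.1 to 27.9), Pdyn (8.76 CPM against 15.3 to 16.1) and Scnn1a (6.17 CPM against 8.30 to 8.60).

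The same library had high levels of genes known from reactive astrocytes. Of 22 genes of reactive astrocytes, 18 were tested and WT replicate 2 was the highest of the 8 libraries in 14. Gfap, the astrocyte intermediate filament, reached 1805 CPM there against 442 to 578 CPM in the other 7 libraries, Cd44 48.3 CPM, Timp1 8.85 CPM and Socs3 9.54 CPM.

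Choroid plexus or meningeal tissue in the sample is argued against as the whole source of the reactive genes in WT replicate 2: the 4 libraries with at least as much choroid plexus or meningeal signal had reactive scores of at most 0.32 against 1.35, a gap of 3.74 SD of the other 7 libraries. For choroid plexus this rests on 1 library, KO replicate 2, with a choroid plexus score of 1.84 against 1.57 and a reactive score of -0.31. The others of the 4 entered by their meningeal signal alone, among them KO replicate 4 with the 0.32. The astrocyte list without Gfap stood at -0.12 relative to the median of the other 7 libraries. That score follows the share of astrocytes only if its genes keep their level per cell in the reactive state. This was not tested, so a larger share of astrocytes stays open. A KO sample under a WT label is argued against by a Dclk3 level 4.23 times that of the highest KO library. What also stays open is a state of that one hippocampus, such as local injury, or a handling difference. No such state was tested, because the pattern is in 1 library and follows no group of the design. The library also carried the lowest dentate granule cell score, so it may add to the difference of that list, which camera with a preset correlation still called without it.

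In WT replicate 3, Col6a4 was lowest at 0.129 CPM against 0.696 to 0.810 in the other 3 WT libraries. Npnt was lowest there too, at 27.3 CPM against 31.0 to 31.3. Cfap44 was highest in that library, at 4.98 CPM against 3.65 to 3.87, and so was Kdm5d, at 26.7 CPM against 22.7 to 23.3. In WT replicate 1, Rpl34 was highest at 33.0 CPM against 28.9 to 29.2, and Hmgcs1 was lowest at 234.4 CPM against 278 to 287.

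In KO replicate 2, Calml4 of the choroid plexus was highest at 10.3 CPM against 2.34 to 3.63 in the other 3 KO libraries, and the doublecortin family score was lowest at -0.037 against -0.0063 to -0.00030. KO replicate 1 had the highest score of astrocyte markers, 0.19 against -0.034 to -0.019, and of thalamic and habenular markers, 0.30 against -0.092 to -0.034. KO replicate 4 had the lowest score of sex-linked genes, -0.43 against 0.084 to 0.18.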

How the results depend on the processing

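Under the planned and added alternatives, 2139 values for single genes and lists, with the count at an unadjusted p, kept their direction and their side of the threshold, 45 passed it only under an alternative, 62 lost it, 47 changed direction and 4 counts moved by over 1.5 times. As edgeR called 0 genes in the main fit, no single gene could lose the threshold. The 62 that lost it were therefore all values of the 11 lists called there. The 2139 kept values do not show that those list calls are stable. Of the values that answer a comparison, 101 kept theirs, 19 counts moved by over 1.5 times or from 0, and 3 values passed the threshold only under an alternative. The threshold on genes at an unadjusted p near Dclk3, and leaving out libraries for the count at an unadjusted p, were added after the data had been seen. Sex as a covariate was not run, since every library held Y-linked counts, and pseudocounts did not apply to counts. Low depth limits Col6a4, Gm10754, Gpr151, Ifi44, Ifit1 and Atp5l, which rest on under 150 counts per library. The cause of the differences listed here was not tested, except that a missing library removes 1 of 4 values and that a stricter threshold calls fewer lists by construction.

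The number of genes called, 0 in edgeR, was 5 with DESeq2 (4 higher and 1 lower in KO, 1 of them within 20 Mb of Dclk3) and ranged from 0 to 1 when a library was left out. For genes higher, genes lower and calls near Dclk3 that range was also 0 to 1. The gene was 1520401A03Rik without WT replicate 1, Dclk3 without WT replicate 2, Col6a4 without WT replicate 3 and the lincRNA C78859 without KO replicate 4. Near Dclk3, 34 genes had an unadjusted p under 0.05. The log2 fold change of Dclk3 was -1.80 with DESeq2 and lay between -1.88 and -1.54 with a library left out. Genes at an unadjusted p under 0.05, 1000 in edgeR, numbered 1505 with limma-voom and between 556 and 1777 with a library left out.

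With the replicate number as a block, edgeR called 1 gene, Dclk3 (1 lower, log2 fold change -1.76, adjusted p = 0.00339; over all alternatives from 5.25e-14 to 0.997), and Eif2s3y stood at -0.061. The numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.14, 0.12, -0.22 and -0.01 across genes, which are not independent, and 1 of 4 WT libraries correlated best with its own number.

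Lists called, 11 with the preset correlation, numbered 5 at an adjusted p under 0.01, 0 with an estimated correlation, 0 with fry, and 6 to 13 with a library left out. Sign changes occurred in genes and lists that had not been called. For a list, a change of sign means that camera turned its direction, which the median did not always follow. With upper quartile factors Ddx3y stood at 0.0021. With the 1 CPM filter camera placed interferon-stimulated genes higher, while their median of 0.0067 was above 0 as in the main fit. With the choroid plexus score as a covariate, camera placed the choroid plexus list lower, while its median shrank from 0.30 to 0.025 and stayed above 0. With 1 surrogate variable, Uty stood at 0.025, Kdm5d at -0.071 and Eif2s3y at -0.48, and list medians were 0.088 for immediate early genes, -0.022 for cortical, -0.050 for thalamic and habenular, 0.0032 for chromatin, 0.017 for heat shock and 0.0075 for channel genes. Oxidative phosphorylation subunits were then called lower, at -0.032 (camera adjusted p = 0.0122). With limma-voom and quality weights, Gpr151 stood at 0.056 and Ddx3y at 0.046. List medians were then -0.0079 for endothelial and mural and -0.011 for thalamic and habenular genes. Interferon-stimulated and sex-linked genes were placed higher by camera, with medians of 0.056 and 0.070. The medians of these lists were above 0 in the main fit too.

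With a library left out, log2 fold changes ranged from -0.0060 to 0.53 for Msx1, -0.38 to 0.58 for Calml4, -0.54 to 0.11 for Gpr151, -0.11 to 0.024 for Uty, -0.054 to 0.028 for Ddx3y and -0.23 to 0.40 for Eif2s3y. List medians ranged from -0.47 to 1.12 for choroid plexus, -0.21 to 0.79 for fibroblast and meningeal, -0.16 to 0.045 for immediate early, -0.054 to 0.17 for cortical, 0.0055 to 0.12 for thalamic and habenular, and -0.047 to 0.17 for ependymal genes. They ranged from -0.035 to 0.14 for endothelial and mural, -0.071 to 0.069 for interferon-stimulated, -0.013 to 0.093 for oxidative phosphorylation, -0.028 to -0.0055 for chromatin and -0.012 to 0.080 for sex-linked genes.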

Other observations

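The tests of noncoding genes and of genes near Dclk3 reported here were set up after the pattern had been noticed but before their own results were seen, except that the share within 5 Mb was weighed, and the splits for the number of genes called were counted, after the result was known.

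Noncoding genes lay higher than protein-coding genes in KO against WT by 0.14 in median log2 fold change. Low abundance is argued against as the whole cause, since the noncoding median lay 0.055 above the upper end of the middle 95% of 10000 lists of protein-coding genes matched on abundance, although those lists had a median of 0.07 themselves. GC content and transcript length are argued against as well, with a difference of 0.13 left after correction for both. Unspliced RNA, from nuclei or pre-mRNA, remains a candidate explanation for the 200 noncoding genes that lie on the same strand as an overlapping protein-coding gene, whose median of 0.34 is 0.22 above the 0.13 of 584 noncoding genes with no overlap (permutation p = 1e-05, the smallest that 100000 permutations can give; genes are not independent), but those 584, and 592 on the opposite strand with a median of 0.10, also lay above protein-coding genes, which this contrast leaves open. Chance among the libraries could not be excluded either, since 7 of 35 splits, the real one included, gave as large a difference, up to 0.191. A difference by genotype stays open.

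Genes at an unadjusted p under 0.05 were more frequent within 20 Mb of Dclk3 than elsewhere. The higher level of noncoding genes is argued against, since protein-coding genes alone gave an odds ratio of 1.90 (Fisher exact p = 0.00268). DNA of another mouse strain around the targeted gene cannot be told apart from other causes: 1 of 65 other windows of 40 Mb with at least 100 tested genes had as high a share, as that explanation requires, yet the odds ratio was 0.80 within 5 Mb, where such DNA would most surely be found. Chance could not be excluded by splits of the libraries: 5 of 35, the real one included, gave as many genes in the window, up to 59. That count rises with the number of genes passing anywhere, so it does not measure the excess near Dclk3. The splits with 59, 54 and 47 genes in the window had 2345, 2739 and 2271 passing over all, against 1000 in the real split. As a share of all genes passing, those splits lay below the real one. The split that set WT replicates 1 and 3 with KO replicates 2 and 4 lay above it, with 11 genes in the window and 187 over all. No test was made on that share. Col6a4, with the highest log2 fold change of the named genes and 5.42 Mb from Dclk3, would be the gene to examine for strain variants, which counts per gene do not show.

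For genes at an unadjusted p under 0.05, splits of the 8 libraries into 4 and 4 did not let chance be excluded. Of 35 splits 9, the real one included, reached the 1000 of the real split. The highest number was 2739, in a split that set WT replicates 1 and 3 with KO replicates 1 and 2. Nor was chance excluded for lists called with the preset correlation, where 8 of 35 splits, the real one included, reached 11, up to 19. The number of genes called cannot be tested in this way, because the real split called 0 and all 35 splits reach that by definition. Among the splits that mix genotypes, the highest number called was 23, with WT replicates 1, 2 and 4 and KO replicate 4 against the rest. Calls in such a split may come from a structure among the libraries that genotype does not follow, which was not tested.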
